A study of Arabidopsis thaliana with 2 samples.

How the data were processed

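The series holds 2 Agilent 2-colour expression arrays of Arabidopsis rosettes, each with a TCP15-EAR and a wild-type sample on it. Replicates are labelled biological, and the dyes are exchanged between the arrays. The spot and background intensity values of both dyes were read from the scanned images with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes, and were deposited as scanned. The processed intensity values in the same files had spatial detrending and linear and LOWESS dye normalization, per the file headers. The log10 ratios in those files are Cy5 over Cy3 of the processed signals, as deposited. The value columns deposited with the series are log2 ratios, and how they were made is not given in the sources used here. By their sign at the spike-in probes (correlation with Cy5 over Cy3 of -0.998 in replicate 1 and 0.998 in replicate 2) both of its columns run in the direction TCP15-EAR over wild type, and they correlated with the ratios computed here at 0.990 and 0.915.

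Mean spot signals and median local backgrounds were taken into R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8). Background was subtracted by normexp with an offset of 50, and each array was normalized by loess with control spots given no weight. No step between arrays was used for the ratios. Log2 ratios were turned to TCP15-EAR over wild type. Spots called outliers by the scanner software (7 and 6 on the 2 arrays) were left out, spots of a probe were averaged, and a probe was kept when it was well above background in at least 1 genotype on both arrays, by the scanner software's own test, which left 30883 probes. Of 43603 probes, 35439 were assigned to 1 locus (34222 by a RefSeq accession in the files and 1217 by a locus name in the files), 475 matched several loci and 7689 none, so that 25855 loci had a probe. Names came from the TAIR10.1 annotation, and the genome build of the probe coordinates is not given in the sources used here. Probes of a locus were averaged, which gave 19738 genes tested, 6039 of them with at least 2 probes. The strand of a probe was not considered: 169 of the probes used, in 162 genes, have coordinates that run against the RefSeq probes of their locus, and these are in 0 of the named genes and 6 list members. Probes with several loci or none stayed out of the gene tests. There were 0 unused columns of per-sample values.

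Well above background were 68.9% of Cy5 and 71.2% of Cy3 spots in replicate 1, and 71.3% and 69.2% in replicate 2. Of the genes tested, 142 were not well above background in TCP15-EAR on either array and 453 not in wild type. For a named gene of this kind the text gives a lower bound, computed from single-channel log2 values after loess and Aquantile, with the dim genotype raised on each array to at least the lowest level of any spot called well above background in that channel.

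The genotype effect was the mean of both ratios, tested with limma's lmFit and eBayes (1 residual degree of freedom, 5.02 prior degrees of freedom) and the Benjamini-Hochberg adjustment at 0.05. The median SE was 0.12 (5th to 95th percentile 0.12 to 0.18), and the smallest absolute log2 ratio that passed was 0.46. By chance 986.9 genes are expected at an unadjusted p under 0.05, and 5925 were found. The dye contrast used the same fit with the sign of 1 array turned. Lists of genes were tested with camera at a preset correlation of 0.01, adjusted over 28 lists, and counts of their members were also taken after adjusting over the list alone. Of these lists 27 were written gene by gene (431 genes) and the cytosolic ribosomal list by annotation.

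Genes named in the text are TCP15, the 12 with the largest increases and the 12 with the largest decreases among those past the threshold and changed the same way on both arrays, and of each list up to 4 members past the threshold with the largest absolute ratio, or the 2 with the largest ratio where 0 passed. A gene at a bound ranks by its bound. Lists, naming rule, comparisons and alternatives were fixed before the data were examined, except where the text says otherwise. On simulated arrays with 200 of 19738 genes changed (20 simulations), the fit recovered 6.72% of genes changed 1.5-fold, 78.7% at 2-fold and 99.5% at 4-fold. It made 14.4 false calls per simulation, and 0.7 calls on average when no gene was changed. The data gave 2941 calls, so these rates, from far fewer changed genes, do not describe recovery in the data. Simulated lists of 20 genes shifted by 0.5 on the log2 scale were called in 100% of cases and unshifted ones in 3.45%. The simulated genes varied independently, so the 3.45% does not cover lists whose members vary together.

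Alternatives covered the background correction, the scanner software's processed signals and log ratios, the log2 ratios deposited with the series, median centring, Aquantile, scaling of the ratios, 2 filters on background, the brightest probe or each probe, leaving out the probes that run against the RefSeq probes of their locus (chosen after seeing the data), an intensity trend in eBayes, channels as separate samples without the array as block, each replicate left out, an unadjusted p, limma's treat with a minimum fold of 1.5, and camera with an estimated correlation, fry and cameraPR for the lists.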

Results

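Rosettes of Arabidopsis thaliana plants carrying P15::TCP15-EAR were compared with wild-type rosettes by 2-colour expression arrays. TCP15 is a class I TCP transcription factor, and the EAR motif is a short peptide that turns the factor it is fused to into a repressor. The fusion was driven by the TCP15 promoter, and the question was which transcripts differ in plants that carry it. Whole rosettes were collected 25 days after germination from soil-grown plants under 16 h of light at 22 to 24 °C, and both genotypes are labelled Col-0. There were 2 arrays, each holding 1 biological replicate of each genotype, with the dyes exchanged between them: wild type was in Cy5 in replicate 1 and in Cy3 in replicate 2. In replicate 1, 30164 wild-type and 31171 TCP15-EAR spots were well above background. In replicate 2 these were 30322 and 31239 of the same 43803 non-control spots. No spot was saturated, and the number of arrays limits the precision. Ratios below are TCP15-EAR over wild type on the log2 scale, as the mean of both arrays ± the standard error (SE) of the limma fit (n = 2 arrays).

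The probes for TCP15 itself (AT1G69690) differed in direction. The probe that starts at nucleotide 1154 of the transcript (chromosome 1, 26217378 to 26217437, build not given in the sources used here) was 4.24-fold higher in TCP15-EAR, with a log2 ratio of 2.09 ± 0.15 and values of 1.90 and 2.27 on the 2 arrays. The probe that starts at nucleotide 1474 (26217698 to 26217757) was lower, at -0.59 ± 0.13, with -0.71 and -0.47. Both probes passed when each probe was tested on its own (limma adjusted p = 0.00217 and 0.0473). Another TCP15 probe, between them (26217618 to 26217677), comes from a separate transcript record and its coordinates run the opposite way. It was not well above background in either genotype, read 0.06 and was not used. Whether either measured probe reads the transgene's transcript is not given in the sources used here. The mean of the 2 measured probes gave 0.75 ± 0.13 for the gene (adjusted p = 0.0169), a value that stands for neither probe. The gene did not pass with an offset of 16 (0.74), with median centring (0.84) or with both arrays scaled to the same spread (0.88).

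**Figure D1:**
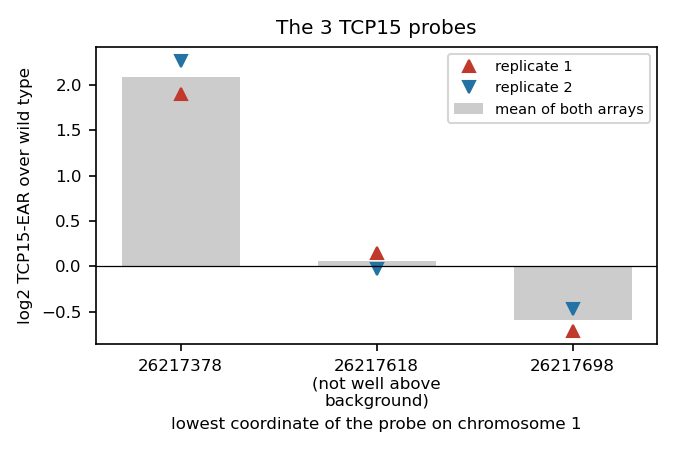
Log2 ratio of TCP15-EAR over wild type for the 3 TCP15 probes, by the probe's lowest coordinate on chromosome 1; bars are the mean of both arrays and triangles the single arrays. The probe at 26217378 lies at 1.90 and 2.27, the one at 26217698 at -0.71 and -0.47.

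Gene lists of anthocyanin synthesis and leaf senescence were higher in TCP15-EAR rosettes, and those of SAUR, growth-related bHLH, expansin and cytokinin response genes were lower, in camera with a preset correlation. None of these calls held with an estimated correlation (adjusted p = 0.586 each). That test rests on 1 residual degree of freedom and called 0 of the 28 lists even at an unadjusted p under 0.05. It could hardly call any list, so the loss alone does not show that list members vary together. Estimated correlations rest on the same 1 residual degree of freedom. They were 1 for floral organ, 0.818 for flavonoid and anthocyanin and 0.436 for aliphatic glucosinolate genes, against the preset 0.01. For the other lists called they lay between -0.0909 (growth bHLH) and 0.0909 (photosynthesis). Where members do vary together, camera's p at the preset correlation is too small. Lipid-transfer protein LTP4 (4.07 ± 0.27) and the nitrilase gene NIT2 (3.63 and 4.38 on the 2 arrays) had the largest increases, and the deacetylase homolog LpxC2 (-5.41 ± 0.17) and the RPW8-like gene HR4 (-5.38 ± 0.24) the largest decreases, with the background correction used here. With the scanner software's centred signals other named genes led, AT5G43570 at 6.26 (LTP4 4.93) and AT3G48080 at -7.65 (HR4 -6.31). AT3G48080 was not well above background in TCP15-EAR on either array, so its value and rank there are not exact. Without a filter on background LpxC2 was at -3.69. In all, 2941 of 19738 genes tested (14.9%) passed an adjusted p of 0.05, 1599 higher and 1342 lower. Of these, 928 changed at least 2-fold. Across genes the ratios of the 2 arrays correlated at r = 0.779. Without regard to a test, 585 genes were changed at least 2-fold the same way on both arrays, 338 higher and 247 lower. The contrast of the dyes, which sets the 2 arrays against each other, gave 0 such genes. In limma it gave 0 genes past adjusted p 0.05 and 11 with an unadjusted p under 0.05, against 986.9 expected by chance. The spread in that fit holds the genotype effect, so it could hardly call a gene and is no control for the 2941.

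The count rested on the pooled spread between 2 arrays and on the normalization. With median centring in place of loess it was 841, of which 68.8% were higher against 54.4% with loess. After scaling both arrays to the same spread it was 0 in limma (3894 with an unadjusted p under 0.05), with 402 genes changed at least 2-fold on both. On 1 array alone, 1305 genes (replicate 1) and 842 genes (replicate 2) reached 2-fold.

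**Figure D2:**
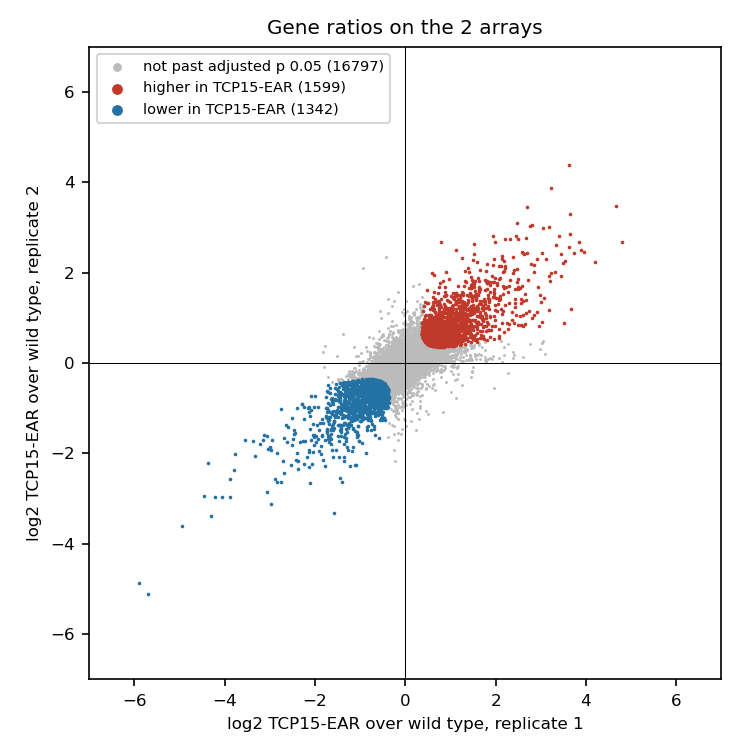
Log2 ratio of TCP15-EAR over wild type of 19738 genes in replicate 1 (horizontal) and replicate 2 (vertical); coloured points passed adjusted p 0.05. Red marks the 1599 higher and blue the 1342 lower genes.

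The 12 genes with the largest increases had varied annotations. Besides LTP4 (AT5G59310, chromosome 5, 23925686 to 23925745), which belongs to the lipid-transfer proteins of the cell surface, and NIT2 (AT3G44300), which can convert nitriles to auxin, they included GPT2 (AT1G61800, 3.55 ± 0.18), a glucose-6-phosphate carrier of plastids. DFR (AT5G42800, 3.25 ± 0.20) and UGT79B1 (AT5G54060, 8.60-fold, SE 0.17 on the log2 scale) are enzymes of anthocyanin synthesis and modification. XTH15 (AT4G14130, 3.21 ± 0.33) remodels xyloglucan in the wall, with probes at 2.37 and 4.04. AT5G43570, annotated as a serine protease inhibitor, was at 3.75 ± 0.45 and was well above background on 1 of the 2 wild-type arrays. The germin-like AT5G39180 (3.47 ± 0.13) and the FAD-binding AT5G44440 (3.27 ± 0.26) were each also well above background in both genotypes. AT2G47780, with a rubber elongation factor annotation, reached 3.20 ± 0.30, AT1G02470 3.11 ± 0.12 and the uncharacterized AT3G28320 was 8.60-fold higher (log2 3.63 and 2.58 on the 2 arrays). Adjusted p of these 12 genes lay between 0.000819 and 0.00521.

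The 12 largest decreases included several genes with no assigned function. LpxC2 (AT1G24880, chromosome 1, 8777871 to 8777930 for its first probe), a homolog of a bacterial lipid A enzyme, was 42.4-fold lower. HR4 (AT3G50480, chromosome 3, 18734105 to 18734164) was 41.6-fold lower, with probes at -6.70 and -4.05. QQS (AT3G30720, -4.27 ± 0.29), which affects starch content, was well above background on 1 of the 2 TCP15-EAR arrays. EXO84B (AT5G49830, -3.71 ± 0.33) is a subunit of the exocyst complex, UMAMIT44 (AT3G28130, -3.51 ± 0.25) a nodulin MtN21-like transporter with probes from -4.55 to -1.47, and MSRB6 (AT4G04840, -3.04 ± 0.12) a methionine sulfoxide reductase. The leucine-rich repeat gene AT3G43740 was at -3.59 ± 0.28 and the RNA-recognition-motif gene AT1G73490 at -3.23 ± 0.29. Uncharacterized AT1G23960 (-3.85 ± 0.22), AT3G47250 (-3.43 ± 0.22) and AT3G45443 (-3.08 ± 0.31) complete the set together with the lipase-like AT3G48080. The last was not well above background in TCP15-EAR on either array, so its ratio is a bound that differed between arrays: at least 19.6-fold lower in replicate 1 and 4.64-fold in replicate 2 (adjusted p = 0.00819). Its replicate 2 value equals the measured ratio. For the other 11 the adjusted p lay between 0.000819 and 0.00341. Among the named genes, 14 of the 35 with at least 2 measured probes had probes that differed by more than 1 on the log2 scale.

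**Figure D3:**
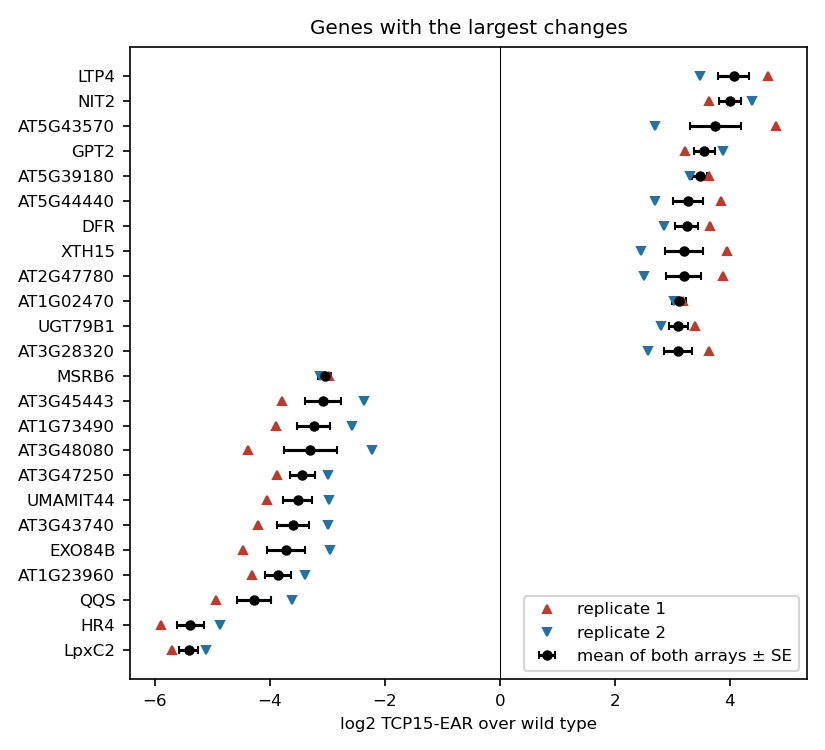
Log2 ratio of TCP15-EAR over wild type for the 12 genes with the largest increases and the 12 with the largest decreases; black points with bars are the mean of both arrays ± SE and triangles the single arrays. Values run from -5.41 (LpxC2) to 4.07 (LTP4).

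By count, the genes lower by at least 4-fold on both arrays were unevenly spread over the chromosomes, and this spread was not tested. Of these 29, 13 were on chromosome 3, 8 on chromosome 1, 6 on chromosome 5, 2 on chromosome 4 and 0 on chromosome 2. Of the 53 higher genes, 16 were on chromosome 1, 8 on chromosome 2, 6 on chromosome 3, 7 on chromosome 4 and 16 on chromosome 5. Chromosomes 1 to 5 hold 26.3%, 15.4%, 19.8%, 15.2% and 23.4% of the tested genes. HR4, QQS, UMAMIT44, AT3G43740, AT3G45443, AT3G47250 and AT3G48080 are among the 13 on chromosome 3. So is RPS15AD, whose probes stood at -5.26 and -0.22.

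**Figure D4:**
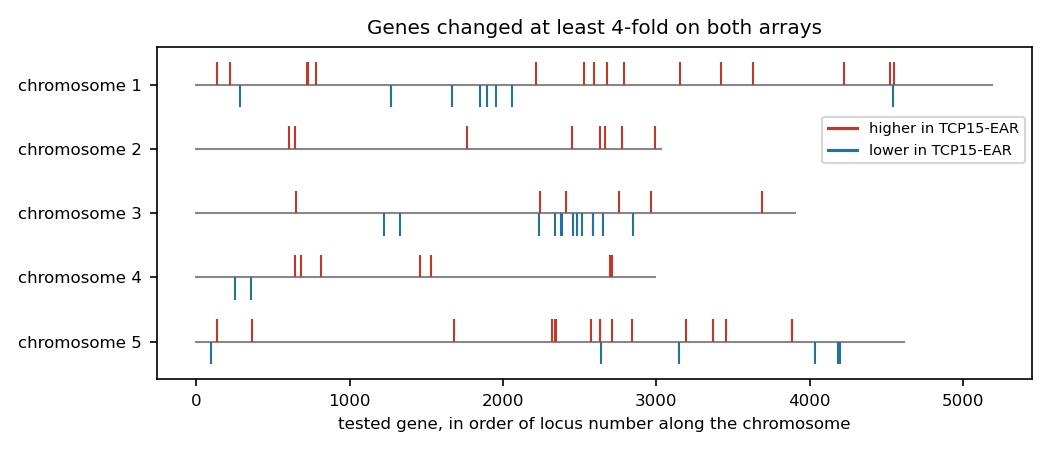
Genes changed at least 4-fold on both arrays, by their place among the tested genes of each chromosome in order of locus number (horizontal); red marks above the line are higher and blue marks below the line lower in TCP15-EAR. Of the 29 lower genes 13 lie on chromosome 3, against 6 of the 53 higher genes.

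Most SAUR and growth bHLH genes measured were lower. Of the 19 SAUR genes measured, a family of short auxin-induced transcripts tied to cell expansion, 13 fell, 0 rose and 6 did not pass (median log2 -0.72, 16 fell when adjusted over the list alone). SAUR64 (AT1G29450, -1.86 ± 0.12), SAUR63 (AT1G29440, -1.71 ± 0.13), SAUR67 (AT1G29510, -1.70 ± 0.15) and SAUR50 (AT4G34760, -1.66 ± 0.12) fell most. The growth-related bHLH genes gave 8 lower and 3 not passed of 11 (median -0.66, 9 lower adjusted over the list alone). Among the lower were PRE6 (AT1G26945, -2.13 ± 0.12), BEE3 (AT1G73830, -1.28 ± 0.13), BEE2 (AT4G36540, 2.14-fold lower, log2 SE 0.13) and HBI1 (AT2G18300, -1.04 ± 0.14). Of 9 alpha-expansins, wall-loosening proteins, 4 were lower (6 adjusted over the list alone, median -0.59): EXPA8 (AT2G40610, -2.03 ± 0.12, probes from -2.77 to -0.59), EXPA5 (AT3G29030, -1.26 ± 0.13, probes -1.94 and -0.57), EXPA11 (AT1G20190, 2.15-fold lower, log2 SE 0.16) and EXPA6 (AT2G28950, -0.81 ± 0.12). The expansin median was -0.24 in replicate 1 and -0.89 in replicate 2. Camera, which sets a list against all other genes, gave adjusted p of 1.61e-11 for SAUR, 3.21e-06 for the bHLH genes and 0.00123 for the expansins. For each of these lists it gave adjusted p = 0.586 with an estimated correlation, which rests on 1 residual degree of freedom. SAUR lost its call there (camera unadjusted p = 0.0926) although its estimated correlation, 0.0175, was near the preset 0.01. Fry, a rotation test, called 0 of the 28 lists (11 at an unadjusted p under 0.05, SAUR and the bHLH genes among them but not the expansins).

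The auxin response list went both ways: 6 of its 12 genes fell and 4 rose (7 and 4 adjusted over the list alone), and the list as a whole did not pass (median -0.50, camera adjusted p = 0.158). IAA3 (AT1G04240, -2.28 ± 0.12), IAA19 (AT3G15540, -1.42 ± 0.12), IAA17 (AT1G04250, -1.23 ± 0.12) and IAA5 (AT1G15580, -1.20 ± 0.14), which encode repressors of auxin signalling that are themselves induced by auxin, were the largest. In the cytokinin response list, 9 of 15 genes fell and 3 rose (11 and 4 adjusted over the list alone, median -0.88, camera adjusted p = 0.000638, and 0.586 with an estimated correlation). The type-A response regulators ARR7 (AT1G19050, -1.72 ± 0.12), ARR16 (AT2G40670, -1.49 ± 0.13) and ARR4 (AT1G10470, -1.48 ± 0.12) and the cytokinin oxidase CKX4 (AT4G29740, -1.41 ± 0.18) were lower. The 3 that rose, named after their values were seen, were the oxidases CKX5 (1.13 ± 0.17), CKX7 (0.94 ± 0.12) and CKX1 (0.69 ± 0.14). Gibberellin genes did not move as a list (median 0.13, adjusted p = 0.693, 3 higher and 2 lower of 14, 3 and 4 adjusted over the list alone). The receptor gene GID1B (AT3G63010, 1.01 ± 0.12) and the inactivating oxidases GA2OX2 (AT1G30040, 1.00 ± 0.13, probes 0.45 and 1.54) and GA2OX6 (AT1G02400, 0.95 ± 0.20) were higher, and the DELLA gene GAI (AT1G14920, -0.62 ± 0.12) was lower.

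Most anthocyanin synthesis transcripts rose. Of 22 flavonoid and anthocyanin genes 14 were higher, 1 was lower and 7 did not pass (17 higher and 1 lower adjusted over the list alone, median 1.05). DFR and UGT79B1 led, followed by the MYB activator MYB75 (AT1G56650, 2.94 ± 0.24) and the anthocyanin malonyltransferase AT5MAT (AT3G29590, 2.56 ± 0.28). The lower gene was the flavonol glycosyltransferase UGT78D1 (-1.38 ± 0.18), named after its value was seen. Leaf senescence genes gave 9 higher of 11 and 0 lower (10 higher adjusted over the list alone, median 1.65). They include the NAC factors ORE1 (AT5G39610, 2.53 ± 0.14) and NAP (AT1G69490, 2.25 ± 0.12), the asparagine synthetase ASN1 (AT3G47340, 4.28-fold, log2 SE 0.20) and SEN1 (AT4G35770, 1.83 ± 0.12). Photosynthesis genes were modestly lower, with 9 of 22 past the threshold and 0 higher (14 lower adjusted over the list alone, median -0.46). LHCB2.3 (AT3G27690, -0.85 ± 0.16) and LHCB1.1 (AT1G29920, -0.80 ± 0.16) encode antenna proteins, and RBCS1B (AT5G38430, -0.77 ± 0.13) and RCA (AT2G39730, -0.70 ± 0.13) a Rubisco subunit and its activase. Camera adjusted p was 8.47e-09, 8.08e-09 and 3.52e-06 for the pigment, senescence and photosynthesis lists. It was adjusted p = 0.586 with an estimated correlation for each of them. The pigment list had a median of 1.24 in replicate 1 and 0.85 in replicate 2. Its estimated correlation was 0.818, so its p at the preset correlation may be far too small.

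**Figure D5:**
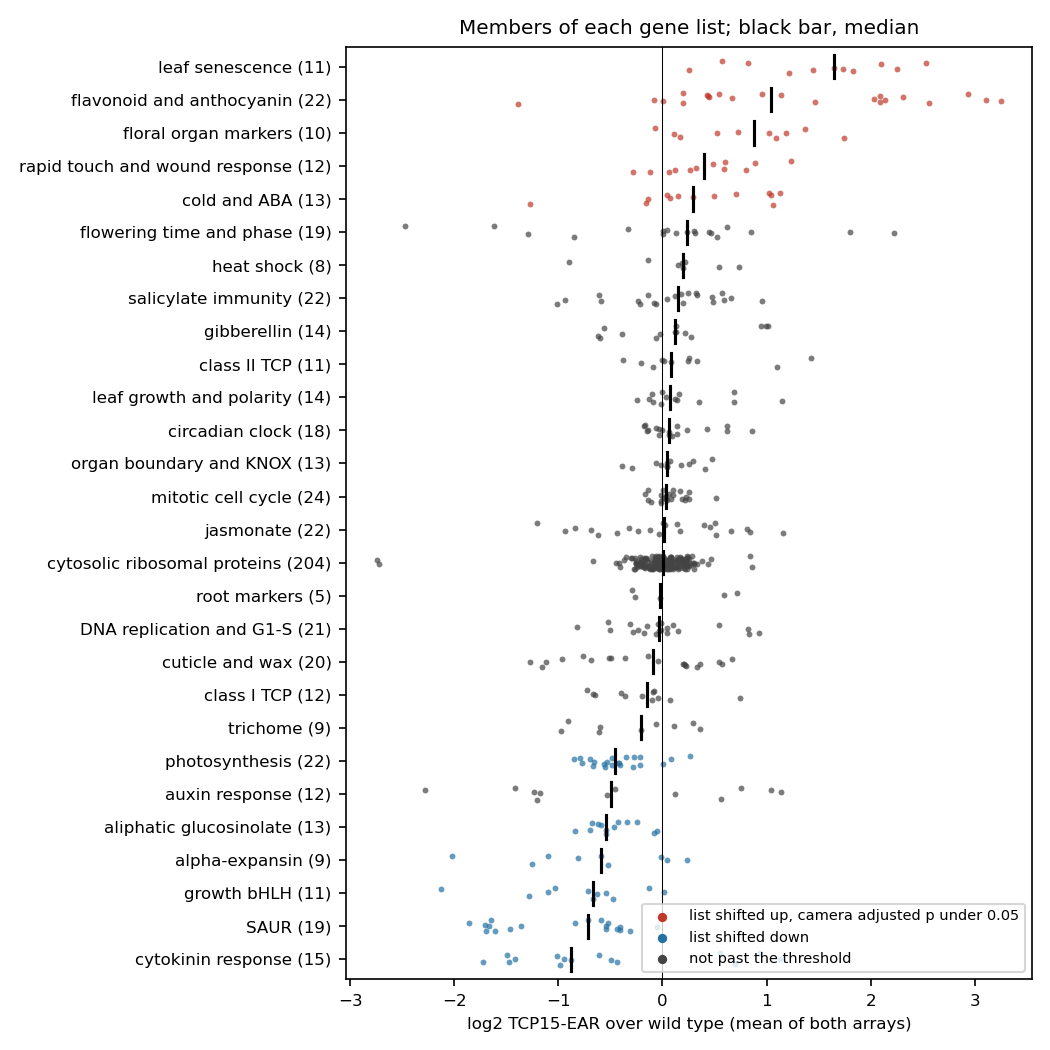
Log2 ratio of TCP15-EAR over wild type (mean of both arrays) of the measured members of each of the 28 gene lists, with the number measured in brackets; each point is a gene, the black bar is the median, and colour marks lists past a camera adjusted p of 0.05. Medians run from -0.88 (cytokinin response) to 1.65 (leaf senescence).

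Flowering regulators changed in both directions. SPL4 (AT1G53160, 2.22 ± 0.12) and FUL (AT5G60910, 1.80 ± 0.13), which promote the floral transition, were higher. MAF4 (AT5G65070, -2.47 ± 0.26) and MAF2 (AT5G65050, -1.62 ± 0.12), which delay it, were lower. MAF4 was well above background on 1 of the 2 TCP15-EAR arrays, and the MAF2 probes ran from -3.03 to -0.88. The flowering time and phase list had 5 higher and 4 lower of 19 (7 and 4 adjusted over the list alone) and did not pass (median 0.23, adjusted p = 0.298). Floral organ genes were higher, 6 of 10 with 0 lower (7 higher adjusted over the list alone, median 0.88, adjusted p = 0.000416, and 0.586 with an estimated correlation). SEP3 (AT1G24260, 1.74 ± 0.22), SEP1 (AT5G15800, 1.19 ± 0.22, probes 0.61 and 1.77) and SHP1 (AT3G58780, 1.09 ± 0.15) were among them. STK (AT4G09960) was not well above background in wild type on either array, and at least 3.80-fold higher in replicate 1 and 1.76-fold in replicate 2 (adjusted p = 0.0201). These STK values equal the measured ratios, since its wild-type signal was not below the lowest level used for a bound. The floral organ genes had a median of 1.11 in replicate 1 and 0.58 in replicate 2. Anther transcripts were measured beside them: 7 of 21 anther markers were well above background in TCP15-EAR on both arrays and 4 in wild type.

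Within the TCP family, most genes did not pass. TCP7 (AT5G23280, -0.73 ± 0.13), TCP14 (AT3G47620, -0.67 ± 0.12, probes -1.20 and -0.14) and TCP21 (AT5G08330, -0.64 ± 0.12) were lower, TCP15 was the 1 called higher, by the mean of probes that differ in sign, and 8 of the 12 measured did not pass. The counts were equal when adjusted over the list alone, and the class I list did not pass (median -0.15, adjusted p = 0.0738). Of 11 class II genes, 2 were higher and 9 did not pass, as also adjusted over the list alone (median 0.08, adjusted p = 0.298). These were the branching repressor TCP18, also known as BRC1 (AT3G18550, 1.42 ± 0.19, probes 0.52 and 2.32), and TCP12 (AT1G68800, 2.14-fold, log2 SE 0.15). Of the 13 organ boundary and KNOX genes 0 passed in limma (3 with an unadjusted p under 0.05), with CUC2 (AT5G53950) at 0.48 ± 0.13 and CUC3 (AT1G76420) at 0.41 ± 0.12 (median 0.05, adjusted p = 0.526, 0 adjusted over the list alone). Both genes passed with no background subtraction (0.88 and 0.70) and with the deposited log2 ratios (1.15 and 0.75), and with the scanner software's signals they stood at 2.41 and 1.04. The 2 CUC2 probes stood at 0.08 and 0.88. Leaf growth and polarity genes gave 3 higher of 14 in both counts, all genes and adjusted over the list alone (median 0.07, adjusted p = 0.298): GRF5 (AT3G13960, 1.15 ± 0.13), PHB (AT2G34710, 0.69 ± 0.12) and ANT (AT4G37750, 0.69 ± 0.16).

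Cell division genes mostly did not pass. Of 24 mitotic cell cycle genes 0 passed in limma, also adjusted over the list alone (1 with an unadjusted p under 0.05), and MAP65-3 (AT5G51600, 0.52 ± 0.13) and CYCA2;4 (AT1G80370, 0.26 ± 0.12) had the largest ratios (median 0.04, adjusted p = 0.483). MAP65-3 passed with no background subtraction (0.59). The DNA replication and G1-S list had 4 higher and 1 lower of 21 (4 and 3 adjusted over the list alone). KRP2 (AT3G50630, 0.92 ± 0.13), an inhibitor of cyclin-dependent kinases, and the D-type cyclins CYCD3;2 (AT5G67260, 0.83 ± 0.12) and CYCD3;3 (AT3G50070, 0.82 ± 0.12) were higher, and the replication helicase subunit MCM6 (AT5G44635, -0.82 ± 0.14) was lower. That list's median (-0.03) and test direction were negative and its mean (0.01) positive (adjusted p = 0.789). Cytosolic ribosomal protein genes, taken by annotation text, served as a broad control: 200 of 204 did not pass, 1 was higher and 3 were lower, with 0 and 2 adjusted over the list alone. Their median was 0.00327 and their mean -0.01, with a negative test direction (adjusted p = 0.825). RPS15AD (AT3G46040) was at -2.74 ± 0.12, but its probes stood at -5.26 (chromosome 3, 16915535 to 16915594) and -0.22 (16914602 to 16914893). AT5G43640 (-2.73 ± 0.13) and RPL3B (AT1G61580, -0.67 ± 0.12) were lower and AT2G07715 (0.86 ± 0.19) was higher. AT2G07715 is annotated as 60S ribosomal protein L2, and its place among cytosolic genes rests on that text alone.

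Epidermal genes fell in part. Of 20 cuticle and wax genes 7 were lower and 2 higher (9 and 3 adjusted over the list alone, median -0.09, adjusted p = 0.178). The cutin hydroxylase CYP86A4 (AT1G01600, -1.28 ± 0.12), the MIXTA-like regulators MYB106 (AT3G01140, -1.16 ± 0.13) and MYB16 (AT5G15310, -1.11 ± 0.12) and CER2 (AT4G24510, -0.96 ± 0.12) of wax elongation were the largest. In the trichome list 3 of 9 were lower (4 adjusted over the list alone, median -0.21, adjusted p = 0.166): GL1 (AT3G27920, -0.97 ± 0.18), GIS (AT3G58070, -0.91 ± 0.12) and ZFP8 (AT2G41940, -0.61 ± 0.12).

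Aliphatic glucosinolate genes were all on the negative side, 13 of 13, but 1 passed on its own, the regulator MYB28 (AT5G61420, -0.68 ± 0.13), and 3 adjusted over the list alone (median -0.54, adjusted p = 0.00123, and 0.586 with an estimated correlation). The list's median was -0.11 in replicate 1 and -0.93 in replicate 2. Rapid touch and wound genes gave 5 higher of 12 (6 adjusted over the list alone, median 0.40, adjusted p = 0.00813, and 0.586 with an estimated correlation), with the zinc finger genes ZAT12 (AT5G59820, 1.24 ± 0.19), SZF1 (AT3G55980, 0.89 ± 0.12) and ZAT10 (AT1G27730, 0.81 ± 0.17) and the touch-induced TCH4 (AT5G57560, 0.60 ± 0.12). Cold and ABA genes gave 5 higher and 1 lower of 13 (6 and 1 adjusted over the list alone, median 0.29, adjusted p = 0.0465, and 0.586 with an estimated correlation). COR47 (AT1G20440, 1.13 ± 0.14), KIN1 (AT5G15960, 1.06 ± 0.12) and KIN2 (AT5G15970, 1.04 ± 0.21) were higher and the dehydrin gene LTI30 (AT3G50970, -1.27 ± 0.13) was lower. The cold and ABA call was lost under most other settings too, with adjusted p from 0.0546 with scaled arrays to 0.198 with median centring.

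Neither salicylate immunity genes (2 higher, 0 lower of 22 in limma, 8 with an unadjusted p under 0.05, 0 adjusted over the list alone, median 0.15, adjusted p = 0.601) nor jasmonate genes (2 higher, 1 lower of 22 in both counts, the second adjusted over the list alone, median 0.02, adjusted p = 0.789) shifted as lists. Their medians turned sign between arrays, from -0.22 in replicate 1 to 0.46 in replicate 2 for salicylate and from 0.41 to -0.30 for jasmonate. SARD1 (AT1G73805, 0.65 ± 0.13) and EDS1 (AT3G48090, 0.49 ± 0.12) of salicylate signalling were higher. JAZ10 (AT5G13220, 1.15 ± 0.25) and TAT3 (AT2G24850, 0.84 ± 0.12) were higher and the defensin PDF1.2 (AT5G44420, -0.84 ± 0.19) lower. JAZ10 was at 1.69 in replicate 1 and 0.62 in replicate 2, and PDF1.2 at -0.47 and -1.22, and PDF1.2 did not pass without the array as block (adjusted p = 0.189 with genotype and dye). In the heat shock list (2 higher, 1 lower of 8, also adjusted over the list alone, median 0.19, adjusted p = 0.298) HSP18.2 (AT5G59720, -0.90 ± 0.17) was lower, and HSP17.6C (AT1G53540, 0.73 ± 0.13) and HSFA2 (AT2G26150, 0.54 ± 0.12) were higher. HSP17.6C did not pass without the array as block (adjusted p = 0.113 with genotype and dye). Of 18 clock genes 3 were higher and 0 lower (4 higher adjusted over the list alone, median 0.06, adjusted p = 0.308): ELF4 (AT2G40080, 0.86 ± 0.12), COR27 (AT5G42900, 0.62 ± 0.13) and BOA (AT5G59570, 0.62 ± 0.13). Root markers, included to look for other tissue, had 0 past the threshold in limma among 5 measured, also adjusted over the list alone, and 2 with an unadjusted p under 0.05. PYK10 (AT3G09260) was at 0.71 ± 0.24 and NRT2.1 (AT1G08090) at 0.59 ± 0.22, with 1.23 and 1.05 in replicate 1 against 0.19 and 0.12 in replicate 2. NRT2.1 passed with no background subtraction (0.75) and with the scanner software's signals (1.46). The list's median was -0.02, its mean 0.14 and its test direction positive (adjusted p = 0.876).

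As a technical control, 10 spike-in probes of fixed Cy5 over Cy3 content were read on both arrays. After normalization their log2 dye ratios differed between arrays by a median of 0.09 and at most 0.66. The scanner software's own summary gave slopes of 0.806 and 0.801 of observed against stated log ratios, so its ratios were compressed. The ratios computed here were not set against the stated ones.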

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

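The tests on neighbouring genes, on the clock and on dye bias were chosen only after the results they address were seen. The tests on single probes and on anther genes were fixed before.

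A signal appeared in probes that the gene comparison does not use, because the reference gives them no locus. The probe described in the file as RPW8.2 was 50.7-fold higher in TCP15-EAR (log2 5.67 ± 0.28, 6.28 and 5.05 on the 2 arrays, adjusted p = 0.00135) and was well above background in both genotypes on both arrays. RPW8.2 is a mildew resistance gene known from other accessions, and Col-0 carries HR4 at that place. The reference used here holds 0 genes of that symbol. HR4 was 41.6-fold lower. Of 2972 probes with no locus, 39 were at least 2-fold higher on both arrays and 34 at least 2-fold lower.

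Some of the decreases sit near each other: among the 29 genes lower by at least 4-fold on both arrays, 8 pairs, made by 12 of the genes and by neither LpxC2 nor HR4, lay within 50 tested genes of each other, against 2.02 after random placing, an excess of 3.96 (permutation p = 0.002, 10000 permutations, and 0.005 without RPS15AD, whose other probe is flat). For the 53 higher genes it was 11 pairs against 6.95, an excess of 1.58 (permutation p = 0.091), and the difference between the excesses was not tested. A candidate explanation is that the TCP15-EAR line carries chromosome segments of another accession, with RPW8.2 in place of HR4, although both genotypes are labelled Col-0. Tandem copies or neighbours regulated together could give such pairs too, as could an effect of the transgene, and neither was tested. A sequence difference under single probes cannot be told apart from a change in transcript: a flat probe stood beside a lower one in 5 of 29 loci and beside a higher one in 5 of 29 (Fisher's exact p = 1, odds ratio 1, 95% interval 0.201 to 4.97).

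Floral organ genes were higher in TCP15-EAR, a call lost with an estimated correlation on 1 residual degree of freedom (camera adjusted p = 0.586). Flower buds in these samples cannot be told apart from expression in leaves, since 7 of 21 anther markers were well above background in TCP15-EAR on both arrays, between the bounds set beforehand, and 4 in wild type. The 7 had a median log2 ratio of 0.32 and 0 passed in limma. Of them ACOS5, CYP704B1 and A9, which gives the median, were not well above background in wild type on both arrays, so their ratios are not exact. LAP5 was at 2.18 in replicate 1 and 0.18 in replicate 2, and ACOS5 at 1.92 and 0.09, so any such tissue may differ between replicates.

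For the shifts of the SAUR, growth bHLH, photosynthesis and leaf senescence lists, 2 technical explanations were tested. A harvest at another time of day would move the clock, and the median absolute log2 ratio of 18 clock genes was 0.137 (0.181 over all genes), with CCA1 at -0.06, LHY at -0.17, TOC1 at 0.06 and GI at 0.14, which argues against a large shift, though ELF4 (0.86), COR27 (0.62) and BOA (0.62) were called higher. A dye bias common to both arrays cancels in their mean, and bias on 1 array alone would make the part that turns with the dyes as large as the part that stays with the genotype. The largest ratio of these parts was 0.242 (growth bHLH), which argues against bias on 1 array as the sole source of the shift in these 4 lists. It cannot exclude bias that adds to a change with genotype. At 0.583 for alpha-expansin and 0.788 for aliphatic glucosinolate genes, between the bounds of the test, bias on 1 array stays open. Leaf age and developmental stage at harvest stay open and untested, and so does an effect of the transgene itself.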

How the results depend on the processing

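The alternatives restricted to genes with at least 2 probes that all changed alike on both arrays, and without probes that run against the RefSeq probes of their locus, were chosen after seeing the data, and the others before. The latter gave 2950 genes, 590 genes and 11 lists for the 3 counts below, with TCP15 at 0.75. Where a value below moved, the cause was not tested unless stated.

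The count of 2941 genes was 4638 with no background subtraction, 1515 with an offset of 16, 4484 with the deposited log2 ratios, 841 with median centring (579 higher and 262 lower, 2131 at an unadjusted p under 0.05) and 0 in limma with scaled ratios (3894 unadjusted). It was 5925 without adjustment, 417 with treat at a minimum fold of 1.5, and 1138 of 2909 genes when limited to genes whose probes change alike, where fewer genes were tested. That limit keeps genes by the signs of the same ratios, which favours genes that pass. The share is therefore inflated, and the count is no check of the 2941. It stayed within 1.5 times with the scanner software's signals (3856 centred, 3893 not), no filter (2573), the stricter filter (3279), the brightest probe (2773), each probe (3411) and an intensity trend (3033). Aquantile leaves ratios as they are and tests nothing. The ratio within an array is the pairing in this design, and with channels as 4 separate samples and no array block the count was 3049 with genotype only and 3884 with genotype and dye.

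The count of 585 genes at least 2-fold the same way on both arrays was 981 with no background subtraction, 2041 and 2047 with the scanner software's signals, centred and not, 1264 with the deposited log2 ratios and 134 with genes whose probes change alike. On single arrays it ranged from 842 to 1305. No test can be made with 1 array, since no residual degrees of freedom remain. The dye contrast gave 0 genes in limma in all 8 alternatives run (10 to 40 at an unadjusted p under 0.05). The spread in its fit holds the genotype effect there too, so these counts are no control. Without regard to a test, the dye contrast held 1 gene at least 2-fold on both arrays with no background subtraction. With the scanner software's signals it held 10, centred and not, and in the other alternatives run 0.

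TCP15 was no longer past the threshold with an offset of 16 (0.74), median centring (0.84) and scaled ratios (0.88). With each probe on its own the lower probe had the opposite sign (-0.59), because the 2 probes differ in sign. On single arrays it was 0.60 to 0.90.

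Of 28 lists 11 passed, and 10 to 12 in every other alternative except 3: 0 in camera with an estimated correlation (0 at an unadjusted p under 0.05), 0 in fry (11 unadjusted), and 5 of 17 with genes whose probes change alike. The 11 unadjusted in fry are not the 11 that passed. They include class I TCP, auxin response, flowering time, organ boundary and root markers. They leave out flavonoid and anthocyanin, photosynthesis, floral organ, aliphatic glucosinolate and alpha-expansin genes. With an estimated correlation, a test on 1 residual degree of freedom, adjusted p was 0.586 for each of the 11 that passed with the preset one. In fry it was 0.0950 for SAUR, leaf senescence, growth bHLH, cytokinin response and cold and ABA, 0.230 for flavonoid and anthocyanin, 0.193 for photosynthesis, 0.257 for floral organ, 0.450 for aliphatic glucosinolate, 0.211 for alpha-expansin and 0.121 for rapid touch and wound genes. The cold and ABA list lost its call with no background subtraction (median 0.29), an offset of 16 (0.29), the scanner software's signals (0.28 centred, 0.28 not), the deposited log2 ratios (0.29), median centring (0.23), scaled ratios (0.28), an intensity trend (0.29), no array block (0.29 in both), ranks (adjusted p = 0.0598) and genes whose probes change alike (0.50). Class I TCP passed with the deposited log2 ratios (-0.29), each probe (-0.14) and no array block with genotype and dye (-0.15), and auxin response with median centring (-0.43). With genes whose probes change alike, cuticle and wax passed (-0.60), and floral organ (1.19), growth bHLH (-0.79) and rapid touch (0.37) did not. Members there were kept by the signs of the same ratios, so calls gained or lost in that subset are no check of a list.

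Medians on single arrays ranged from -0.92 to -0.62 for cytokinin response, 0.10 to 0.16 for flowering time, 0.20 to 0.21 for heat shock, 1.37 to 1.51 for leaf senescence, 0.048 to 0.074 for organ boundary, 0.39 to 0.49 for rapid touch, -0.77 to -0.73 for SAUR, -0.31 to -0.14 for class I TCP, 0.067 to 0.19 for class II TCP, 0.27 to 0.39 for cold and ABA, -0.011 to 0.16 for mitotic and -0.50 to -0.35 for photosynthesis genes. In replicates 1 and 2 they were -0.24 and -0.89 for alpha-expansin, -0.11 and -0.93 for aliphatic glucosinolate, 1.11 and 0.58 for floral organ, -0.55 and -0.90 for growth bHLH, -0.37 and -0.61 for auxin and -0.11 and -0.31 for trichome genes. They were 0.11 and 0.00334 for leaf growth and polarity, 0.20 and 0.00207 for gibberellin and 0.04 and 0.11 for clock genes. The sign turned for salicylate (-0.22 and 0.46), jasmonate (0.41 and -0.30), DNA replication (-0.08 and 0.02), ribosomal (0.08 and -0.05), root (-0.05 and 0.02) and mitotic genes.

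Of the 115 named genes besides TCP15, 0 had the opposite sign under any setting, but the log2 ratio of 39 moved over 1.5 times under at least 1 alternative with both arrays, which the SE does not cover. The ratio ran from -7.42 to -4.14 for QQS, -7.66 to -3.12 for AT3G48080, -6.19 to -3.60 for EXO84B, -5.70 to -2.98 for AT3G45443, 1.25 to 4.96 for STK and 3.63 to 6.26 for AT5G43570, each farthest from 0 with the scanner software's signals. AT3G48080 in TCP15-EAR and STK in wild type were not well above background on either array, so their ratios are not exact. Of the 109 past the threshold, 0 passed under all 16 tested settings, since scaling called none, 59 when scaling is left out, and 89 when median centring and the offset of 16 are left out as well. Of the 6 not past it, CUC2, CUC3, MAP65-3 and NRT2.1 passed with no background subtraction and with the deposited log2 ratios, CUC2, CUC3 and NRT2.1 with the scanner software's signals, CUC2 and MAP65-3 with the stricter filter, CUC2 with the brightest probe and MAP65-3 with an intensity trend. Without an array block CUC2, CUC3 and PYK10 passed (genotype and dye), and CUC3 with genotype only, while HSP17.6C and PDF1.2 lost their calls in both and KIN2 with genotype only. On single arrays 14 of the 115 had a ratio over 2 times that on the other array. Of these, 12 were past the threshold: JAZ10, PDF1.2, GA2OX6, AT2G07715, ANT, KIN2, STK, SEP1, ZAT10, LHCB1.1, HSP18.2 and GL1. Signal over background limits 142 genes in TCP15-EAR and 453 in wild type to bounds.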

Other observations

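The families below were grouped by their annotation text, and they and their tests were chosen only after the gene results were seen. Of 24 families 8 passed in camera with a preset correlation and are given below, and 16 did not. With an estimated correlation 0 of the 24 passed in camera (0 at an unadjusted p under 0.05), with adjusted p of 0.613 for 7 of the 8 and 0.638 for NAC factors. That test rests on 1 residual degree of freedom and could hardly call any family.

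Arabinogalactan proteins, glycoproteins of the cell surface, were lower in 22 of 43 genes and higher in 2 (median log2 -0.63, camera adjusted p = 1.13e-06), among them AGP4 (-1.66), FLA9 (-1.56) and FLA13 (-1.52). The wider SAUR-like family had 23 lower and 6 higher of 63 (median -0.35, adjusted p = 4.58e-06). Lipid-transfer proteins had 21 higher and 7 lower of 64 (0.26, adjusted p = 0.00133), led by LTP4 (4.07) and its neighbour LTP3 (3.09). Nodulin MtN21 transporters had 11 higher and 1 lower of 37 (0.41, adjusted p = 0.00133), with UMAMIT20 (1.75) and UMAMIT29 (1.73). NAC factors had 17 higher and 1 lower of 68 (0.15, adjusted p = 0.00336), with ORE1 (2.53), NAP (2.25) and NAC019 (1.93), of which ORE1 and NAP are also on the senescence list. WRKY factors had 11 higher and 2 lower of 59 (0.19, adjusted p = 0.00470), with WRKY28 (1.76), WRKY45 (1.41) and WRKY75 (1.33).

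With the preset correlation these 6 families passed with the same direction in all 16 alternatives to the processing and fit. Among the 16, Aquantile and the intensity trend repeat the main ratios and the same camera test. They add nothing to this count or to the counts that follow. Glutaredoxins (7 lower and 1 higher of 41, -0.16, adjusted p = 0.0270) passed in 14, and glutathione S-transferases (10 higher and 2 lower of 51, 0.18, adjusted p = 0.0419, with GSTU24 at 2.39) in 11. Medians in replicates 1 and 2 were -0.43 and -0.19 for SAUR-like, 0.33 and 0.23 for MtN21, 0.29 and 0.17 for lipid-transfer, 0.11 and 0.27 for WRKY and 0.11 and 0.21 for glutathione S-transferase genes. Over the alternatives the lipid-transfer median ran from 0.20 to 0.81, that of MtN21 from 0.29 to 0.69 and that of SAUR-like genes from -0.75 to -0.28.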
